A study of Mus musculus with 4 samples.

How the data were processed

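The series holds 4 RNA-seq libraries of CD11b-positive cells isolated from mouse brain with magnetic beads, all in 1 group. The submitters' protocol describes PLX5622, an inhibitor of the receptor kinase CSF1R, given for 7 days, and cells taken after 10 further days without the drug, 17 days in all, from mice aged 10 to 13 weeks. Libraries were made from 300 ng of total RNA with a strand-marking kit after poly(A) selection, per the labels' protocols. No other group was analysed here, so levels and the spread between libraries are reported and no effect of the drug is estimated. The labels number the libraries 1 to 4, and those numbers name them below. The labels do not say whether each library came from a separate animal, so p-values measure only the spread between these samples, which may be technical.

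The authors deposited a table of raw counts per Ensembl gene, with 1 column per library. Per the submitters' processing notes, bcl2fastq 2.20.0.422, STAR 2.7.2b and featureCounts 1.6.5 were used with the GRCm38 build. The annotation release, the strand setting and the treatment of reads that map to several genes are not given in the sources used here. Genes that share sequence with close copies, and genes that overlap an antisense gene, are therefore uncertain in level. The table holds 55471 genes. Of these, 55230 were matched by identifier to GENCODE M21, which gave the symbols, coordinates and exonic lengths. The remaining 241 stayed in the totals under their identifiers and held at most 0.00526% of the counts of a library. No row of the table was a total or an unassigned class, and no other column of values per sample was present.

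Total counts were 24412573, 23036202, 23585261 and 24487418. A floor of 3 counts corresponds to 0.122, 0.130, 0.132 and 0.119 CPM, the counts of a gene per 1000000 counts of a library. Floors cover counting error only, since reads without molecular identifiers are not independent molecules. CPM were computed on library sizes scaled by the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3. The TMM factors were 1.00, 1.01, 0.963 and 1.03. Gene levels are means ± SD over the 4 libraries. A gene counted as detected at 1 CPM or more in every library.

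The 29 gene lists were fixed before the data were examined, as were the tests and most alternatives. They cover microglial programs (homeostatic microglia, disease-associated microglia, cell cycle, type I interferon response, MHC class II, MHC class I, cytokines and NF-kB targets, immediate early genes, lysosome, complement, CSF1 receptor axis, TGF-beta signalling, cholesterol and lipid handling, housekeeping), other cells that a CD11b isolation could carry (engrafted bone-marrow-derived macrophages, border-associated macrophages, monocytes, neutrophils, T and NK cells, B cells, neurons, astrocytes, oligodendrocytes, oligodendrocyte precursors, endothelial cells, pericytes and smooth muscle, ependyma and choroid plexus, erythroid cells) and sex-linked genes. The level of a list in a library is the median over its members of log2(CPM + 0.5). Its gap to the homeostatic list was tested with an exact two-sided sign-flip permutation over the 4 libraries, whose smallest p is 0.12 (2 of 16 sign flips), so no gap could pass 0.05. The mean level of each list was placed among 10000 random lists of equal size matched on exonic length in 10 bins. These were drawn from all genes with a known exonic length and at least 1 count over the 4 libraries.

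Spread between libraries was tested per gene with a negative binomial goodness of fit in edgeR. The residual deviance of an intercept-only fit with the trended dispersion was set against a chi-square on 3 degrees of freedom, over the 14112 genes kept by filterByExpr. Adjusted p-values are Benjamini-Hochberg values, with a threshold of 0.05. The quasi-likelihood F-test of a coefficient does not apply to a single group. As an alternative, the quasi-likelihood variance of each gene was set against its trended prior with an F distribution on 3 and 2.62 degrees of freedom, and this is called the quasi-likelihood test below. The quasi-likelihood test allows genes to scatter around their trend, and the goodness of fit does not. That prior and the trended dispersion of the goodness of fit were both fitted to the same genes. Neither test is therefore an independent check of the other. Per list with at least 5 tested members, the median deviance was placed among 10000 random lists matched on mean expression in 20 bins, with a one-sided permutation p adjusted over the 27 such lists. Members of a list vary together, which random lists do not reproduce, so this p describes these 4 libraries. In simulated counts for the same 14112 genes and 4 libraries, 200 genes were raised in 1 library each. The gene test found 7 of 100 genes raised 2-fold and 72 of 100 raised 4-fold, with 3 false calls. Falls in 1 library were not simulated. The list test gave p under 0.05 for 6 of 200 unchanged lists and 20 of 20 changed lists. Simulated genes were drawn independently, each with the trended dispersion that the gene test assumes. The simulation therefore cannot show how many false calls arise where genes scatter around that trend or vary together.

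Named genes were chosen by a rule: the 20 genes of highest mean CPM outside mitochondrially encoded and ribosomal protein genes, the 3 highest members of each list, the 6 highest and 2 lowest members of the homeostatic, cell cycle, disease-associated and CSF1 receptor lists, the 25 variable genes with at least 5 CPM and the largest ratio of highest to lowest library, and Csf1r, Itgam, Tmem119, P2ry12, Sall1, Ms4a7, Mki67, Xist and Ddx3y. Some genes that the rule selects are not reported here. Any other gene named was chosen after its values were seen. The share of each gene's transcript made of 50-base words found in no other gene was computed from the GENCODE M21 transcripts. Alternatives covered DESeq2 1.42.0 size factors, total counts, other filters, other estimates of the spread and leaving out each library. For the closing part, further markers of endothelium, mural cells, choroid plexus and meningeal fibroblasts and 13 glycolytic genes were listed before their values were looked at, except that Gapdh and Pgk1 among the glycolytic genes had been seen. Of the further markers, Tm4sf1 and Myl9 also belong to the 25 most variable genes, and the falls were computed with and without them. Pairs of libraries were checked for double deposition. The median squared Poisson difference per gene ran from 1.78 for libraries 2 and 4 to 12.3 for libraries 1 and 3, where counting noise alone gives 0.455, so all 4 were counted as separate samples. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for the annotation and the figures.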

Results

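Brain CD11b-positive cells were profiled by poly(A) RNA sequencing in 4 libraries from mice that had received PLX5622 for 7 days and then 10 days without it. CD11b is the integrin encoded by Itgam and marks microglia and other myeloid cells. PLX5622 blocks CSF1R, the receptor kinase on which microglia depend for survival, and after its withdrawal microglia return to the brain. The submitters named the cells repopulated microglia. Libraries 1 to 4 held 24412573, 23036202, 23585261 and 24487418 counts. In all, 12512 genes, 11776 of them protein coding, reached 1 CPM in every library, and 27874 had at least 1 count. Mitochondrially encoded genes took 1.21%, 1.49%, 1.42% and 1.66% of the counts of libraries 1 to 4.

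The first question the design allows is which microglial genes the isolated cells carried, and at what level. Without another group, returned cells cannot be told from cells that survived the drug. Microglial genes were among the most abundant, and so were Ttr and Enpp2 of the choroid plexus, Ttr with a higher mean than Csf1r. Cst3, a cysteine protease inhibitor, had 15222 ± 4312 CPM (SD, n = 4). Csf1r itself, the target of the drug, stood at 9504 ± 1015 CPM, Cx3cr1, the fractalkine receptor, at 3918 ± 428 CPM, and P2ry12, a purinergic receptor of surveying microglia, at 3230 ± 708 CPM. Tmem119, a microglial membrane protein, had 2428 ± 184 CPM, Sall1, a transcription factor of microglial identity, had 817 ± 132 CPM, and Itgam had 531 ± 75.6 CPM. On GRCm38, Csf1r (ENSMUSG00000024621) spans chromosome 18, 61100598 to 61132149, Tmem119 chromosome 5, 113793729 to 113800516, P2ry12 chromosome 3, 59216272 to 59262871, Sall1 chromosome 8, 89027235 to 89044162 and Itgam chromosome 7, 128062640 to 128118491, from the first to the last exon of each protein-coding gene. All 18 homeostatic genes were detected, down to Slc2a5, a fructose transporter, at 379 ± 63.8 CPM and Mef2c, a transcription factor, at 342 ± 26.4 CPM. The list median was 2047 CPM, with an SD of 0.13 on the log2 scale (n = 4), above every one of the 10000 length-matched random lists, as were 8 other lists. In all, 18 of the 29 lists lay above the 95th percentile, the endothelial, choroid plexus and erythroid lists among them. Random lists also held genes with very few counts, so a high percentile shows little more than expression. None of the 18 homeostatic genes differed between libraries past the threshold in edgeR. At an unadjusted p under 0.05 there was 1 such member, and the quasi-likelihood test and DESeq2 gave 0. Rhob, a small GTPase, had 3415 ± 592 CPM.

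Lysosomal and complement genes were also abundant. Ctss and Ctsd, lysosomal proteases, had 8855 ± 1662 and 5832 ± 1136 CPM, and the lysosome list lay 1.87-fold below the homeostatic list. The C1q chains that start the classical complement pathway had 3941 ± 733 CPM for C1qb, 3823 ± 825 CPM for C1qa and 3348 ± 567 CPM for C1qc, and the complement list lay 3.88-fold below. Other genes among the 20 highest were Serinc3 at 5738 ± 623 CPM, Psap, the precursor of lysosomal saposins, at 5259 ± 782 CPM, Sparc, a matricellular protein, at 4594 ± 445 CPM, the lysosomal protease Lgmn at 4014 ± 474 CPM, the pore-forming protein Mpeg1 at 3994 ± 911 CPM, Itm2b at 3860 ± 574 CPM, the actin-binding peptide Tmsb4x at 3581 ± 1384 CPM and Actb at 3456 ± 353 CPM. Each of the 28 other lists had a lower median than the homeostatic list in all 4 libraries, with an exact sign-flip permutation p of 0.12 for each (2 of 16 sign flips), the smallest the design can give. With counts divided by exonic length, the lysosome list was the 1 exception, with a gap of -0.27 ± 0.44 (log2, SD, n = 4).

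Genes around the drug target were expressed at graded levels. The CSF1 receptor axis had a list median of 7.18 ± 0.30 (log2), with 10 of 12 members detected. Trem2 and its signalling partner Tyrobp had 988 ± 173 and 831 ± 155 CPM, the myeloid transcription factors Irf8 and Spi1 had 497 ± 81.0 and 209 ± 22.5 CPM, and the GM-CSF receptor chain Csf2ra had 181 ± 46.3 CPM. Kit and Flt3, receptor kinases related to CSF1R, had 2.00 ± 1.01 and 2.54 ± 0.508 CPM. TGF-beta signalling, which maintains microglial identity, had a list median of 7.95 ± 0.19, led by the receptors Tgfbr1 at 2126 ± 137 and Tgfbr2 at 583 ± 95.3 CPM and the pathway repressor Ski at 422 ± 60.2 CPM. Cholesterol and lipid handling had a median of 5.01 ± 0.11, with the lipid exporters Abca1 at 510.1 ± 88.0 and Abcg1 at 129 ± 15.8 CPM. The housekeeping list had a median of 5.85 ± 0.14, with Sdha, a subunit of succinate dehydrogenase, at 238 ± 2.75 CPM and the ribosomal protein gene Rplp0 at 361 ± 85.5 CPM. Of the transcript of Rplp0, 58.2% was unique, so its level is uncertain.

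Genes of proliferation were low and genes of the disease-associated state were spread over a wide range. The cell cycle list had a median of 1.61 ± 0.17, 669.8-fold below the homeostatic list, with 19 of 26 members detected. Its highest members were replication licensing genes and the polymerase clamp: Mcm3 at 50.5 ± 5.30, Pcna at 38.6 ± 8.77, Mcm6 at 19.6 ± 0.513, Mcm4 at 16.3 ± 0.526, Mcm2 at 10.5 ± 1.59 and Mcm5 at 9.24 ± 0.689 CPM. Mki67, a marker of cycling cells, had 5.72 ± 1.45 CPM, and the mitotic genes Ube2c and Ccnb1 had 0.711 ± 0.102 and 0.210 ± 0.0617 CPM. The list stood at percentile 11.8 of length-matched random lists. All 19 disease-associated genes were detected, with a list median of 5.94 ± 0.53. Apoe, a lipid carrier, had 1553 ± 360.5 CPM, the tetraspanins Cd9 and Cd63 had 556 ± 67.4 and 127 ± 13.6 CPM, and the receptor kinase Axl had 241 ± 144 CPM. Fabp5, a fatty acid binding protein, had 1.51 ± 0.123 CPM and Ch25h, a cholesterol hydroxylase, had 2.29 ± 0.390 CPM. Unique sequence made up 63.5% of the transcript of Cd63, 68.2% of that of Pcna and 57.9% of that of Ccnb1, and their levels are uncertain. Ccnb1 also had only 3, 5, 6 and 6 counts in libraries 1 to 4, near the floor of 3.

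Stimulus-response and further immune programs were also measured, in cells after isolation. No sample shows their levels before it. The immediate early list, genes induced within minutes of a stimulus, had a median of 9.31 ± 0.17, 3.22-fold below the homeostatic list. Its leading members were Zfp36 at 2942 ± 768, Jun at 2522 ± 613 and Fos at 2017 ± 651 CPM. Cytokines and NF-kB targets had a median of 5.50 ± 0.32, led by the NF-kB inhibitors Nfkbia at 476 ± 102 and Tnfaip3 at 377 ± 114 CPM and the chemokine Ccl3 at 392 ± 141 CPM. MHC class II had a median of 6.95 ± 0.29, with the invariant chain Cd74 at 343 ± 59.4, the peptide loader H2-DMa at 169 ± 18.8 and H2-Aa at 161 ± 62.8 CPM. MHC class I had a median of 7.04 ± 0.20, with B2m at 3253 ± 793, H2-D1 at 1202 ± 577 and H2-K1 at 882 ± 318 CPM. The type I interferon response had a median of 5.35 ± 0.91, with Bst2, a membrane tether of budding virions, at 116 ± 37.1 CPM.

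**Figure D1:**
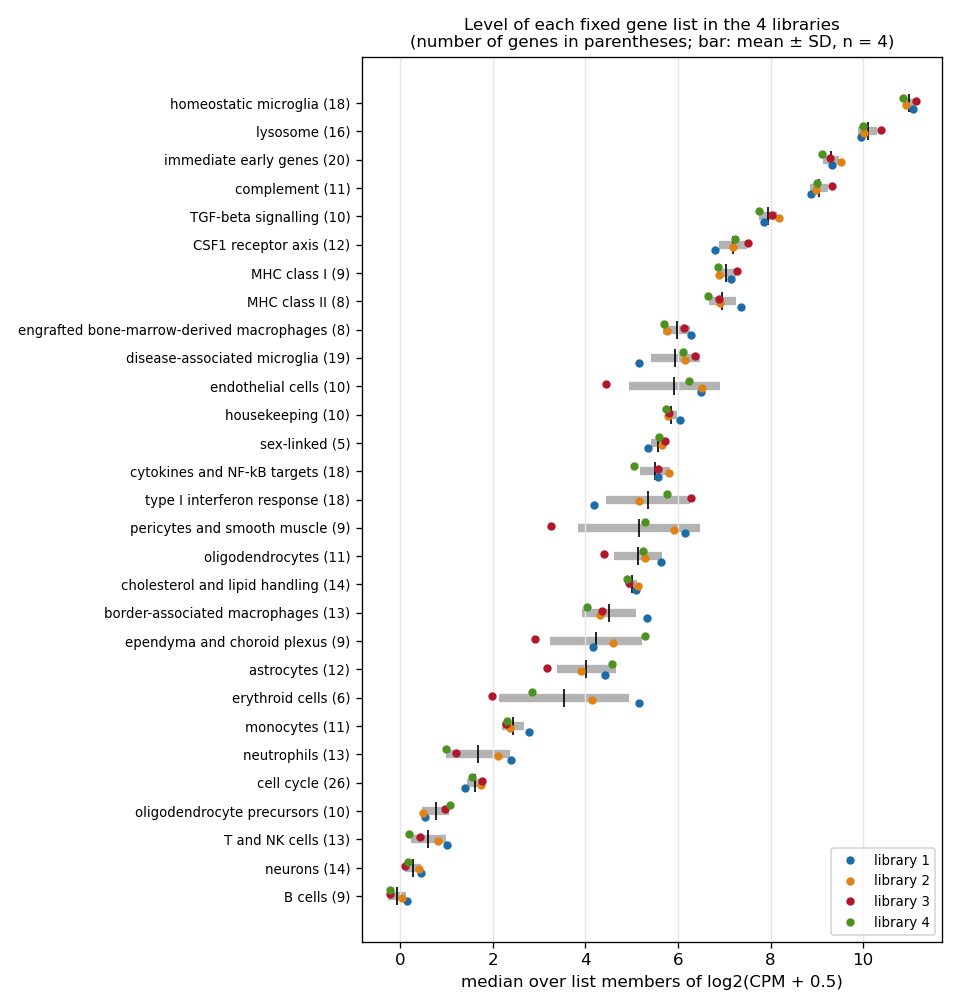
Median over the members of each gene list of log2(CPM + 0.5), on the x axis, for the 29 lists on the y axis, with 1 point per library, a tick at the mean and a bar of ± 1 SD (n = 4). The homeostatic list is highest, and the endothelial, pericyte, choroid plexus and erythroid lists have their lowest point in library 3.

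A second question is which other cells the isolation carried. Most markers of lymphocytes and neurons were low, although Ighm of the B cell list stood at 281 ± 36.8 CPM. The list medians were 0.27 ± 0.17 for neurons, -0.07 ± 0.19 for B cells, 0.60 ± 0.37 for T and NK cells and 0.76 ± 0.29 for oligodendrocyte precursors (log2, SD, n = 4), against a value of -1 for no counts. The highest T and NK genes were the granule protease Gzma at 5.86 ± 4.13 (3.90 without library 1), Il2rb at 3.09 ± 1.08 and perforin (Prf1) at 2.06 ± 0.612 CPM, the highest neuronal genes were Map2 at 8.75 ± 3.83, Stmn2 at 5.53 ± 3.14 and Camk2a at 4.58 ± 0.987 CPM, and the highest precursor genes were Cspg4 at 12.6 ± 6.23, Pdgfra at 7.99 ± 4.70 and Olig1 at 3.84 ± 0.980 CPM. Monocyte markers had a median of 2.43 ± 0.24, with the chemokine receptor Ccr2 at 23.5 ± 2.25, Itga4 at 22.3 ± 4.10 and fibronectin (Fn1), which other cells also express, at 131 ± 67.8 CPM. Neutrophil markers had a median of 1.67 ± 0.69, with the calgranulins S100a9 and S100a8 at 17.2 ± 9.76 and 13.7 ± 7.99 CPM. Csf3r of the same list was far higher, at 823 ± 183 CPM. Markers of engrafted bone-marrow-derived macrophages had a median of 5.97 ± 0.28. It rested in part on genes that microglia also express, such as Apoe and Lyz2 (421 ± 112 CPM), while Tmem176b had 335 ± 67.3 CPM and Ms4a7 had 14.9 ± 11.3 CPM (9.29 without library 1). Border-associated macrophages had a median of 4.51 ± 0.57, with the scavenger receptor Stab1 at 842 ± 92.9, the mannose receptor Mrc1 at 175 ± 77.9 and F13a1 at 80.4 ± 28.2 CPM. Between the highest and lowest library Stab1 differed 1.31-fold and Mrc1 2.39-fold, and which cells carried Stab1 was not tested.

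Choroid plexus, vascular, astrocyte and oligodendrocyte lists had higher medians than the lymphocyte, neuron, oligodendrocyte precursor, monocyte and neutrophil lists. All lay below the engrafted macrophage list (5.97), and choroid plexus and astrocytes also lay below border-associated macrophages (4.51). Ttr, the thyroxine carrier made by choroid plexus epithelium, averaged 9625 ± 5306 CPM, and Enpp2, a lysophospholipase also made there, had 4204 ± 2363 CPM. The ependyma and choroid plexus list had a median of 4.24 ± 0.99. The endothelial list had a median of 5.92 ± 0.99, with Flt1, a VEGF receptor, at 199 ± 97.3, the transporter Slco1a4 at 115 ± 56.6 and the tight junction gene Cldn5 at 89.3 ± 56.9 CPM. The pericyte and smooth muscle list had a median of 5.15 ± 1.32, with Rgs5 at 160.1 ± 85.8, smooth muscle actin (Acta2) at 98.2 ± 65.4 and smooth muscle myosin (Myh11) at 83.9 ± 49.1 CPM. Astrocytes had a median of 4.01 ± 0.64, with the glutamate transporters Slc1a3 at 147 ± 17.3 and Slc1a2 at 39.9 ± 9.29 CPM. Oligodendrocytes had a median of 5.14 ± 0.52, with the myelin genes Mbp at 227 ± 122 and Cnp at 83.1 ± 13.9 CPM. Erythroid genes had a median of 3.54 ± 1.40, with the globins Hbb-bs at 102 ± 99.9, Hba-a1 at 18.6 ± 15.6 and Hbb-bt at 17.2 ± 18.4 CPM. Without library 1 these means were 55.9, 12.1 and 8.42 CPM, and Hba-a1 had 38.2, 23.7, 3.87 and 8.57 and Hbb-bt 43.6, 15.98, 3.08 and 6.19 CPM in libraries 1 to 4. Under 42% of the transcript of each globin was unique, so their separate levels are uncertain. The Y-linked genes Ddx3y, Eif2s3y and Kdm5d had 154 ± 15.4, 101 ± 7.61 and 47.5 ± 5.14 CPM, Xist had 0.170 ± 0.0963 CPM, and the sex-linked list had a median of 5.58 ± 0.16.

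The third question is how far the libraries differed from each other. The biological coefficient of variation was 26.6%, and 463 of 14112 genes (3.28%) varied more than genes of their level at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 1350 genes, and 69.9% of genes had a p over 0.5. Both shares exceed those of evenly spread p-values, so genes scattered around the fitted trend. This test makes no allowance for such scatter, and some calls may be its upper end. Of the 463 genes, 385 (83.2%) stood apart by being lower in library 3, 38 by being lower in library 1 and 21 by being higher in library 1. The count of 463 rests on the model: the quasi-likelihood test called 0 genes, and DESeq2 marked 5 genes as dispersion outliers. In the quasi-likelihood test 658 of 14112 genes had an unadjusted p under 0.05, and the smallest adjusted p was 0.889. The prior of that test and the dispersion trend in edgeR were both fitted to these same genes. The 0 calls do not show that the spread is absent, and the 463 do not settle how many genes vary. The edgeR count was 425, 276, 106 and 258 without library 1, 2, 3 and 4, and 68 of the 106 were among the 463. Of 41 named genes past the threshold, 26 lost it without library 3, 11 without library 1 and 7 without library 2 or library 4, and 5 kept it in all 4 fits. At the level of lists, 12 of 27 varied more than random lists of like expression.

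Interferon-stimulated genes were lowest in library 1 and highest in library 3. All 18 members of the interferon list were highest in library 3 (17 when scaled to the homeostatic list), and 16 were lowest in library 1 (18 with that scaling). The list medians were 4.18, 5.15, 6.29 and 5.77 (log2) in libraries 1 to 4, and the median ratio of library 3 to library 1 over members was 3.32-fold. Oas2, which senses double-stranded RNA and makes the activator of RNase L, had 14.0, 52.4, 145 and 88.9 CPM, Oas3 had 1.71, 6.70, 19.3 and 9.17 CPM, and Ifi204, Ifi213 and Ifi206, of the interferon-inducible p200 family, had 32.2, 58.0, 138 and 86.8, 3.96, 14.7, 41.0 and 21.5 and 1.84, 6.31, 17.3 and 10.1 CPM in libraries 1 to 4. Axl had 74.7, 206, 423 and 258 CPM and H2-D1 490.1, 1135, 1895 and 1287 CPM in the same order of libraries. All 9 MHC class I genes were also highest in library 3 (8 with total counts, 7 with homeostatic scaling), and 4 were lowest in library 1 (7 with homeostatic scaling). The interferon list exceeded random lists in spread (median deviance 5.85 against 0.310, permutation p = 1e-04, the smallest possible, adjusted p = 0.000337), with 10 of 18 members past the threshold over all genes and 15 adjusted over the list alone. Over all genes this count was 4, 8, 7 and 8 without library 1, 2, 3 and 4. The MHC class I list did so too (adjusted p = 0.0087, permutation), with 2 of 9 members over all genes (0 without library 1) and 3 adjusted over the list alone, but not without library 3 (adjusted p = 0.0655). Without library 1, Axl, H2-D1, Oas3, Ifi213 and Ifi206 lost their calls (adjusted p 0.0666, 0.504, 0.653, 0.206 and 0.939). Ifi206 also lost it without library 2 (0.0619) and Ifi204 without library 3 (0.0532). Of the transcript of Ifi204, 69.8% was unique, and its level is uncertain. Every list of vascular, choroid plexus and erythroid markers was at its lowest in library 3, and the border macrophage, erythroid and oligodendrocyte lists were at their highest in library 1.

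**Figure D2:**
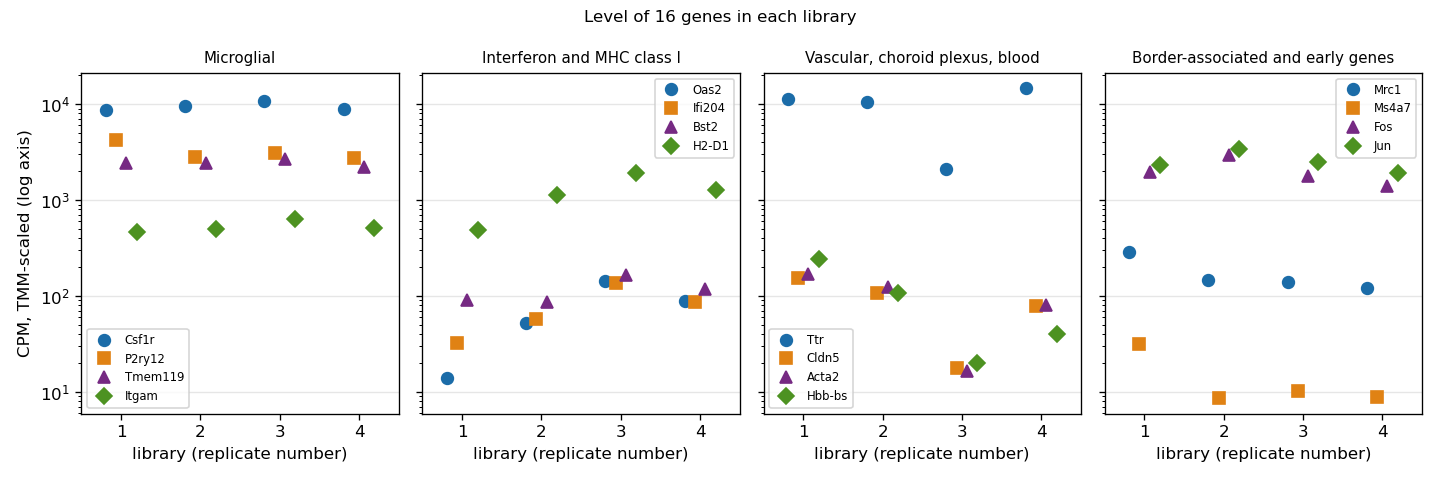
CPM on a log axis for 16 genes in each of the 4 libraries, in 4 panels, with 1 point per gene and library. Interferon and MHC class I genes are highest in library 3, where Ttr, Cldn5, Acta2 and Hbb-bs are lowest, and Mrc1 and Ms4a7 are highest in library 1.

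Vascular, choroid plexus and blood genes were low in library 3. Ttr had 11345, 10479, 2115 and 14562 CPM in libraries 1 to 4, Kl, a choroid plexus co-receptor for FGF23, had 227, 342, 72.3 and 492 CPM, and Folr1, a folate receptor, had 81.5, 70.4, 14.1 and 97.7 CPM. Cldn5 had 154, 107, 17.7 and 78.9 CPM, Acta2 had 170.3, 124, 16.5 and 81.7 CPM and Hbb-bs had 241, 108, 20.1 and 40.01 CPM. Relative to the mean of the other libraries, the median member in library 3 was 4.42-fold lower for endothelial cells, 5.05-fold for pericytes and smooth muscle, 3.67-fold for ependyma and choroid plexus and 4.64-fold for erythroid cells. The erythroid fold depended on the library it was set against, at 7.80, 4.91 and 1.92 for libraries 1, 2 and 4, and was 3.07 without library 1. The erythroid list medians were 5.16, 4.15, 1.98 and 2.85 (log2) in libraries 1 to 4, and 6 of 6 members were highest in library 1 (5 with homeostatic scaling). In library 3, 9 of 10 endothelial, 9 of 9 pericyte, 9 of 9 choroid and 6 of 6 erythroid genes were at their lowest. All 4 lists exceeded random lists in spread (median deviance 10.6, 12.5, 6.58 and 12.0, permutation p = 1e-04 and adjusted p = 0.000337 for each). Over all genes 9, 7, 5 and 5 members passed, and 9, 7, 9 and 5 adjusted over the list alone. Without library 3 the counts over all genes were 0 endothelial, 1 pericyte, 0 choroid and 4 erythroid, and without library 1 the erythroid count was 2. Without library 3 the endothelial list did not pass (adjusted p = 0.0866), nor did Ttr, Enpp2, Kl, Folr1, Cldn5, Flt1, Slco1a4, Rgs5, Acta2 and Myh11, while the other 3 lists and Hbb-bs did. Others of the most variable genes followed the same pattern of a minimum in library 3: the smooth muscle genes Tagln at 50.1 ± 36.8, Myl9 at 44.8 ± 29.4 and Pln at 9.09 ± 6.11 CPM, the endothelial genes Tm4sf1 at 49.2 ± 30.97, Sox18 at 15.4 ± 9.88 and Gkn3 at 11.5 ± 9.54 CPM (7.28 without library 1), Mgp, an inhibitor of calcification, at 34.2 ± 23.997 CPM, Rgs4 at 30.7 ± 18.9, Ltbp1 at 6.88 ± 4.30, Igfn1 at 7.65 ± 5.96 and Bcas1 at 12.2 ± 9.59 CPM (7.87 without library 1), and Slc4a5, Wdr86 and Gmnc at 65.7 ± 44.1, 25.8 ± 17.1 and 11.8 ± 8.35 CPM. Of these 14 genes, Tagln alone kept its call without library 3. Calls were also lost by Bcas1 and Pln without library 1, by Igfn1, Ltbp1 and Sox18 without library 2, and by Igfn1, Gmnc and Wdr86 without library 4.

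Stimulus-response genes tended to be highest in library 2 and border macrophage genes in library 1. Of 20 immediate early genes, 16 were highest in library 2. Fos had 1975, 2925, 1772 and 1395 CPM and Jun 2334, 3370, 2468 and 1914 CPM in libraries 1 to 4, neither past the threshold for single genes. Of 18 cytokine and NF-kB genes, 9 were highest in library 2, and Ccl3 had 482, 542, 275 and 267 CPM. Of 13 border macrophage genes, 12 were highest in library 1 (11 with homeostatic scaling), with Mrc1 at 291, 148, 141 and 121 and Ms4a7, of the engrafted list, at 31.8, 8.64, 10.3 and 8.89 CPM. Both calls were lost without library 1, 2 or 4. Markers of other cells were also highest in library 1, with 6 of 6 erythroid (5 with homeostatic scaling), 10 of 11 oligodendrocyte (7), 9 of 13 T and NK cell (5) and 7 of 11 monocyte genes (5), and so was the neuronal RNA Bc1 at 608, 132, 54.7 and 172 CPM. Of 18 homeostatic genes, 10 were highest in library 1 too, so such a majority is not particular to other cells. Only 3 of 13 T and NK genes were detected, and the T and NK cell and monocyte lists did not exceed random lists in spread (adjusted p = 0.147 and 0.242, permutation). In library 2, 7 of 13 neutrophil genes were highest (10 with homeostatic scaling). The immediate early, cytokine and border macrophage lists exceeded random lists in spread (median deviance 2.43, 3.82 and 3.95, permutation p = 1e-04 and adjusted p = 0.000337 for each), with 6, 6 and 5 members past the threshold over all genes and 8, 9 and 10 adjusted over the list alone. Over all genes the immediate early count was 8, 0, 4 and 3 without library 1, 2, 3 and 4, the cytokine count 5, 0, 5 and 2, and the border macrophage count 0, 1, 8 and 1. The border macrophage list did not pass without library 1 (adjusted p = 0.108).

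Smaller differences in spread were seen for glia and neutrophils. Astrocytes (adjusted p = 0.00891, permutation), neutrophils (0.00933) and oligodendrocytes (0.0324) exceeded random lists, with 3, 2 and 2 members past the threshold over all genes and 4, 4 and 3 adjusted over the list alone. Over all genes the counts were 2, 2, 0 and 1 for astrocytes without library 1, 2, 3 and 4, 0, 0, 4 and 0 for neutrophils, and 2, 2, 0 and 2 for oligodendrocytes. Mbp had 382, 207, 84.0 and 237 CPM and S100a9 23.9, 26.8, 11.9 and 6.23 CPM in libraries 1 to 4. The call for Mbp was lost without library 3, and that for S100a9 without library 1, 2 or 4. Without library 4 astrocytes (0.0884) and neutrophils (0.0572) did not pass, nor did oligodendrocytes without library 2 (0.157). The remaining tested lists did not pass, from disease-associated microglia (adjusted p = 0.0569) to cell cycle (0.989). Among them, 2 disease-associated, 1 complement, 1 engrafted macrophage and 1 monocyte gene passed over all genes, and 3, 2, 1 and 1 adjusted over the list alone. The first count was 0 without library 1 for disease-associated genes, without library 1, 2 or 3 for complement and without library 1, 2 or 4 for engrafted macrophages. Oligodendrocyte precursors had 0 over all genes and 2 adjusted over the list alone, with 2 at an unadjusted p under 0.05 and 0 by the quasi-likelihood test or DESeq2. The homeostatic, cell cycle, MHC class II, lysosome, CSF1 receptor, TGF-beta, lipid, housekeeping, T and NK cell and neuron lists had 0 in edgeR by either adjustment, and without library 3 the T and NK cell list had 1 over all genes. Each had at most 1 member at an unadjusted p under 0.05 there, at most 1 by the quasi-likelihood test, and 0 marked by DESeq2. The B cell and sex-linked lists had too few tested members.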

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

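The tests of scaling and the added scaling to the homeostatic list were chosen after the results were seen. The test on further markers was fixed before the values of those markers were looked at, and its repeat without Tm4sf1 and Myl9, which are also among the most variable genes, was chosen after.

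A library was far from the other 3 when its gap to the nearest, divided by the whole range, exceeded 0.83, Dixon's critical value for 4 samples. This held for 12 of 166 values tested, where chance gives about 1 in 20, or 8.3. Among list medians, the endothelial list was far lower in library 3 (ratio 0.861), the lysosome list was higher in library 3 (0.859) and the housekeeping list was higher in library 1 (0.85). Among genes, H2-DMa (0.945) and Sparc (0.861) were higher in library 3, where Slco1a4 (0.903) was lower. Ccr2 (0.942), Ms4a7 (0.926), Mcm6 (0.861), H2-Aa (0.845) and Mrc1 (0.842) were higher in library 1. The gap ratio takes no account of size. Between the highest and lowest library, with 0.5 CPM added, these genes differed 1.20-fold, 3.53-fold, 1.055-fold, 2.14-fold and 2.39-fold in the same order. Dlk1 (0.939), which encodes a Notch-related membrane protein, was higher in library 4, with 0.979, 1.94, 0.484 and 24.4 CPM in libraries 1 to 4, and its variability call was lost without library 4 (adjusted p = 0.801).

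The low endothelial list belongs to a pattern in which choroid plexus, vascular and erythroid markers were at their lowest in library 3. The tables argue against scaling as the cause for the endothelial list, since over 4 scalings the smallest fall of the endothelial list in library 3 was -2.10 (median log2 ratio to the other libraries). A candidate explanation for the vascular and choroid plexus part is that fewer of these cells came through the CD11b isolation, which should remove them, into library 3, while no further erythroid markers were tested and that part stays open. Further markers were lower too, 4.23-fold for endothelium (9 of 10 genes lowest in library 3), 4.92-fold for mural cells (8 of 8) and 4.78-fold for choroid plexus (10 of 10). The endothelial exception was Eng at 167, 236, 178 and 208 CPM in libraries 1 to 4. Outside the pattern, markers of meningeal fibroblasts were 2.74-fold lower (8 of 8). The smallest of the first 3 falls was -2.08 on the log2 scale, where at least 1 above -0.5 would have argued against the explanation. Without Tm4sf1 and Myl9 it was -2.06, with 4.18-fold for endothelium and 4.28-fold for mural cells. These markers come from the same cell types and libraries as the lists that showed the pattern, so their fall was likely beforehand. They show that the pattern extends to further genes, and they cannot tell fewer cells apart from other causes. In library 3 the median member was 1.53-fold lower for astrocytes (9 of 12 genes lowest in library 3), 1.12-fold for oligodendrocytes (3 of 11, with list medians of 5.63, 5.28, 4.40 and 5.24 in libraries 1 to 4) and 1.11-fold for neurons (5 of 14), and the log2 ratio was 0.05 for oligodendrocyte precursors, while no biological explanation was tested, nor whether intact cells or free RNA carried these transcripts.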

How the results depend on the processing

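The scaling to the homeostatic list, the other scalings of the far-library count, the removal of shared list members, the counts of list members and the gene means with 1 library left out, and the erythroid folds against single libraries were chosen after the data were seen. The count of variable genes depended on the estimate of the spread. It was 463 as reported, 1058 with a common dispersion, 0 with the quasi-likelihood variance (658 at an unadjusted p under 0.05) and 5 by DESeq2 dispersion outliers, and 106 to 425 with 1 library left out. With 3 libraries there are fewer samples, and the cause of the other differences was not tested. Other scalings and filters gave 419 to 492. Counts such as these have no direction, so no reversal could be seen in them. All 25 of the most variable genes lost their call with the quasi-likelihood variance. Csf1r stayed at 9151 to 9777 CPM, detected genes at 9849 to 14345, the coefficient of variation at 0.191 to 0.312, lists past the spread test at 10 to 16, and far list medians at 2 or 3. Oligodendrocytes lost their call with homeostatic scaling (adjusted p = 0.0893). Disease-associated microglia gained one with total counts (0.0449), with the SD of log2 CPM (0.00945) and without library 1 (0.0172), within a range of 0.00945 to 0.554. Without library 1 and without library 3, 5 and 3 lists gained a call. Gaps to the homeostatic list moved by over 1 SD for 20 of 28 lists per kilobase of exon, 14 with means over members, 9 with detected members only and 6 with a prior of 2, and none changed sign. Far list medians need 4 libraries and were not recomputed on 3. No paired analysis was possible because the series holds 1 group. At this depth genes under about 0.13 CPM are not detectable. The gene test found few simulated rises of 2-fold in 1 library, and falls were not simulated.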

Other observations

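The tests of scaling and of carried-over cells for the interferon pattern were chosen after the result was seen. Those of GC content, shared sequence and glycolytic genes were fixed before their results.

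Csf3r and Ighm were far above the other markers of the lists that hold them. Csf3r, the G-CSF receptor used as a neutrophil marker, had 823 ± 183 CPM (SD, n = 4), with 580.3, 839, 1025 and 849 CPM in libraries 1 to 4, while S100a9 and S100a8 had 17.2 ± 9.76 and 13.7 ± 7.99 CPM. Csf3r was lowest in library 1 and highest in library 3, and S100a8 was highest in library 1. Ighm, the constant region of the IgM heavy chain, had 281 ± 36.8 CPM, against 16.7 ± 5.26 CPM for Cd22 and 12.6 ± 4.85 CPM for Cd79b, parts of B cell receptor signalling. Bc1, a short noncoding RNA of neurons, had 608, 132, 54.7 and 172 CPM in libraries 1 to 4 and varied past the threshold (adjusted p = 2.9e-16, edgeR), also in all 4 fits that left out a library, while the neuronal list had a median of 0.27 (log2). Of its transcript, 68.9% was unique. Ribosomal protein genes took 1.08%, 0.721%, 1.09% and 0.801% of counts in libraries 1 to 4.

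The interferon genes were lowest in library 1 and highest in library 3. The tables argue against scaling, since the median log2 ratio of library 3 to library 1 stayed at 1.67 or more over 4 scalings. They also argue against more cells of the listed other types in library 3, where the highest such ratio among those lists was 0.12 (oligodendrocyte precursors). Low values of several of these lists in library 3 were already known, and cell types outside the lists were not tested. GC content or length is argued against too, since the interferon ratio lay at percentile 100 of 10000 lists matched on GC content, exonic length and level. The cause stays open. Differences in handling or time of day are not recorded in the labels used here, and no biological explanation was tested.

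Gapdh, Ppia and Pgk1, chosen after their values were seen, had few counts for genes that every cell uses, at 17.1, 22.3 and 5.05 CPM. For Gapdh and Pgk1 the tables argue against low expression of glycolysis as a whole, since the 8 of 13 glycolytic genes with at least 80% unique sequence had a median of 115 CPM. Reads lost to near-identical copies could be a cause, as 17.5% of the Gapdh transcript, which shares sequence with 218 genes, and 32.0% of that of Pgk1 were unique. Unique share alone did not order these levels, since 72.6% of the transcript of Ppia was unique at 22.3 CPM and 27.8% of that of Eno1, also chosen after its values were seen, at 71.4 CPM. Across 84 ribosomal protein genes, which are not independent replicates, Spearman's rho between unique share and CPM per kilobase was 0.25 (one-sided permutation p = 0.0119), between the 0.1 and 0.3 set beforehand, so this explanation cannot be told apart from others.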
